A study of Mus musculus with 21 samples.

How the data were processed

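The series profiled protein-DNA contacts by CUT&RUN, in which an antibody bound to a chromatin protein in permeabilised cells directs a protein A-micrococcal nuclease fusion to cut and release the nearby DNA for sequencing. The cells were ID8, a mouse line from C57BL/6 ovarian surface epithelium, with intact Trp53 (WT) or with both copies of Trp53, the gene for p53, knocked out (KO). Of 21 samples, 4 used a p53 antibody (2 WT and 2 KO), 16 used antibodies to 4 histone H3 modifications, and 1 was an IgG control in WT cells. Per the labels' protocols, transcription factor libraries were extracted with phenol-chloroform to keep short fragments, and yeast DNA was added as a spike-in.

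The files used here were 6 tables, all of them lists of p53 peaks on mm10 or annotations of such lists. Per the file headers, each peak list deposited by the authors gives only a chromosome, a start and an end, with no score, height, fold enrichment or p-value. The submitters' processing notes name fastp, Bowtie2, MACS2 and deepTools, with mm10 as the genome build. Their versions, settings and order, and the rule by which peaks were called WT-specific, are not given in the sources used here. There was 1 WT list and 1 KO list for 2 samples each, so the values are the authors' values per genotype with no replicate behind them, and no test across samples was possible. The labels name a pooled signal track per genotype, and whether peaks were called on pooled reads is not given in the sources used here. Read depth is unknown, so neither a detection limit nor an interval for read counting can be given. The histone modification and IgG libraries were not analysed here.

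The WT-specific intervals were the same in the BED file, the peak table and both annotation tables. The first annotation table gives 1 feature class per peak (promoter, 5' UTR, 3' UTR, exon, intron or intergenic) with a gene name. The second lists the repeats that overlap each peak, with position, name, class, strand and family. The shortest overlap in that table, computed from its coordinates, was 50 bp. The tool, the promoter definition and the source of either annotation are not given in the sources used here. Start positions were read as 0-based, as in the BED file, and are printed 1-based.

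Lists were compared with bedtools 2.31.1 at a minimum overlap of 1 bp. Shares of peaks carry 95% exact binomial (Clopper-Pearson) intervals, and medians carry 95% intervals from order statistics. These intervals treat peaks as independent draws, cover counting error only, and describe the lists rather than the genotypes. Two-sided Fisher's exact tests across peaks or genes have the same limit. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

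Gene identities came from a RefSeq table of assembly GRCm38.p6, the assembly that mm10 represents. Of 997 gene names in the feature annotation, 758 matched a RefSeq symbol or synonym, 19 more were in an Ensembl name table, and 220 matched neither. The RefSeq table has no strand, so distances to transcription start sites were not computed. Before the data were examined, 13 gene lists (190 genes after merging older names) were fixed: 5 of p53 targets taken from general knowledge, 5 of RNA and DNA sensing, interferon response, antigen presentation, chemokines and cytokines, and repeat silencing, and 3 of neuronal and glial, leukocyte, and fibroblast and endothelial markers. Each list was tested against all 49980 RefSeq genes, with Benjamini-Hochberg adjustment over the 13 lists, and set against 10000 random lists matched on gene length in 10 bins. To treat WT and KO lists alike, a gene was also counted where a peak fell in its RefSeq span with 5 kb added on each side.

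The rule for named genes, also fixed before the data were examined, took every list member with a WT-specific peak, the Trp53 locus, the 10 WT-specific peaks with the highest score, and the highest 5 in an LTR and 3 each in a LINE and a SINE. With no score or fold in the files, peak length took the place of the score, a change made after the files were seen. One gene that the rule names is not reported here. Peak strength was for the same reason described by length alone. No mm10 sequence was used here, so the planned search for p53 motifs was not run, and no genome-wide repeat annotation was used, so repeat shares have no genomic background. The list test was tested on simulated data over 49980 genes at the sizes of the fixed lists, which hold 5 to 24 genes. A list with a 5-fold odds ratio was called in 3 to 16% of simulated sets, depending on its size, a 20-fold odds ratio in 27 to 90% and a 50-fold odds ratio in 71 to 100%. Of 43200 unchanged lists, 0.241% were called. Lists were changed singly in these sets and hits did not depend on gene length, whereas several lists passed together in the data. These rates are therefore only a rough guide to the test as used here. Alternatives covered the overlap rule, the share of a peak that a repeat must cover, the gene background, the promoter class alone, the longer 50% of the peaks, and removal of peaks that overlap a KO peak or lie on chromosome Y.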

Results

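Binding of p53, the transcription factor encoded by Trp53, was mapped by CUT&RUN in ID8 mouse ovarian surface epithelial cells with and without Trp53. The p53 antibody was used on 2 WT and 2 KO samples, and the deposited peak lists hold 1 set of intervals per genotype. The KO list is the background measured with the same antibody. The WT list held 6811 peaks with a median length of 338 bp, and the KO list held 9784 peaks with a median length of 345 bp. A further list, labelled WT-specific, held 2127 peaks, for which the authors gave gene features and repeats. None of the values below has a replicate check, since each comes from 1 list.

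The first comparison asked which p53 peaks depend on Trp53. A KO peak overlapped 4043 of the 6811 WT peaks, 59.4% (95% exact binomial interval 58.2 to 60.5). The other 2768 WT peaks, 40.6%, had no KO peak, against 5770 KO peaks, 59.0% of 9784, with no WT peak. The WT-specific list took in 2056 of the 2768 WT peaks without a KO peak and left out 712. Those left out were short, with a median of 225 bp (95% interval 219 to 228), against 454 bp (444 to 465) for the WT-specific peaks and 286 bp (278 to 293) for the WT peaks that overlapped a KO peak. The WT-specific list also held 71 peaks, 3.34% (2.62 to 4.19), that did overlap a KO peak by at least 1 bp, and their median length was 663 bp. Of the 2127 WT-specific intervals, 2114 were identical to a WT peak.

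At the targeted gene itself, a peak of 293 bp lay at chromosome 11, positions 69579979 to 69580271, which the annotation placed in the promoter of Trp53 (RefSeq gene 22059, positions 69580348 to 69591873). It was in the WT and the WT-specific lists. No KO peak fell within 5 kb of the Trp53 gene. Peak lists give presence and not the level of p53, so this does not measure the knockout.

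Established p53 target genes were found beside WT-specific peaks far more often than other genes. Of 61 genes on the 5 p53 lists, 27 (44.3%) had a WT-specific peak in the deposited annotation, where 0.925 would be expected from the 1.52% of all 49980 genes that had one. The odds ratio was 53.4 (two-sided Fisher's exact test, p = 4.7e-33), and the highest count among 10000 random lists of the same gene lengths was 8. Against protein-coding genes alone, 24 of 56 had a peak where 1.88 would be expected, and the odds ratio was 22.3 (p = 4.42e-21, Fisher's exact test). In that background the odds ratios were 41.8 for the cell cycle and feedback list, 37.5 for cell death and 10.5 for metabolism and stress. The 27 genes carried 34 peaks, 28 of them annotated as promoter. Of the 34, 1 overlapped a KO peak, where 3.34% of all WT-specific peaks did.

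Among genes of cell cycle arrest and p53 feedback, 10 of 17 had a WT-specific peak (odds ratio 94.0, adjusted p = 1.39e-13, Fisher's exact test). They were Cdkn1a, Btg2, Gtse1, Plk2, Ccng1, Mdm2, Mdm4, Trp53inp1, Psrc1 and Ckap2. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (RefSeq gene 12575, chromosome 17, positions 29090979 to 29100722), had a promoter peak of 1800 bp at 29090346 to 29092145 and another of 2094 bp at 29093503 to 29095596. Mdm2, the ubiquitin ligase that degrades p53 (chromosome 10, positions 117688875 to 117710758), had promoter peaks of 1579 bp at 117709250 to 117710828 and of 361 bp at 117711466 to 117711826. The shorter of these overlapped an RLTR23 long terminal repeat. Mdm4, a p53 inhibitor related to Mdm2, had a 5' UTR peak of 1513 bp (chromosome 1, positions 133019256 to 133020768) that also overlapped RLTR23. The Gtse1 promoter peak overlapped an RMER15 LTR, and the Psrc1 promoter peak overlapped RLTR51A_Mm and RMER17C. One of the 2 Plk2 promoter peaks, 1454 bp long, was the peak that overlapped a KO peak.

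**Figure D1:**
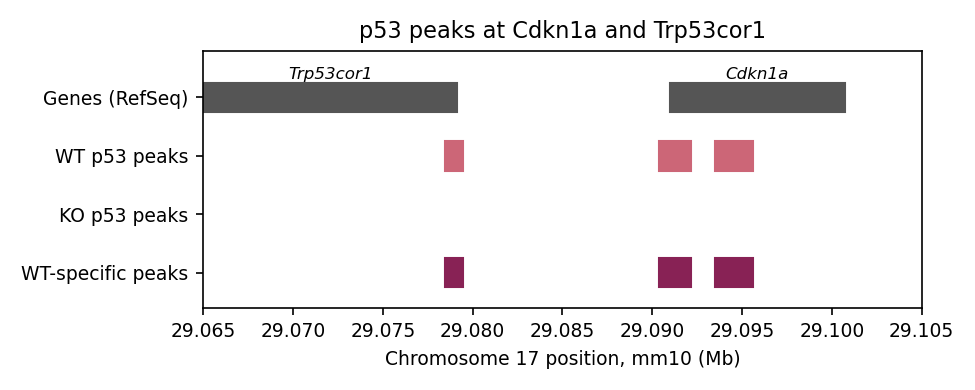
Map of chromosome 17 (mm10, position in Mb) with RefSeq gene spans and the WT, KO and WT-specific p53 peaks as boxes to scale. The 3 WT peaks, at Trp53cor1 and Cdkn1a, are all WT-specific, and the KO row is empty in this region.

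Among cell death genes, 9 of 16 had a WT-specific peak (odds ratio 84.5, adjusted p = 2.74e-12, Fisher's exact test). Bax and Bbc3 (Puma), which promote mitochondrial apoptosis, had promoter peaks of 914 and 1957 bp. The receptor genes Tnfrsf10b and Eda2r had promoter peaks of 216 and 1282 bp. Phlda3, an inhibitor of Akt, and Zmat3, an RNA-binding protein, had 2 promoter peaks each, the longer ones of 2465 and 1549 bp. Aen, Pidd1 and Ei24 had promoter peaks of 1080, 420 and 1139 bp. Of 15 metabolism and stress genes, 4 had a peak (odds ratio 23.7, adjusted p = 0.000204, Fisher's exact test): Ddit4, an inhibitor of mTORC1 signalling, Ak1 and Abhd4 in peaks annotated as promoter, and Ephx1, the microsomal epoxide hydrolase, with 3 intronic peaks. The promoter class is that of the deposited annotation. The Ak1 peak (chromosome 2, 32629429 to 32629949) lay inside its gene (32621758 to 32635058), away from both RefSeq ends, as did the Abhd4 and Pidd1 peaks. Of 5 noncoding RNA genes, 3 had a peak (odds ratio 97.8, adjusted p = 0.000147, Fisher's exact test): Trp53cor1 (lincRNA-p21), Pvt1 and the microRNA gene Mir34b. Of 8 DNA repair genes only Ercc5 had one, and this list did not pass the test (odds ratio 9.29, adjusted p = 0.249, Fisher's exact test).

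Another 6 listed p53 targets had a WT-specific peak within 5 kb of the gene that the annotation gave to a neighbour or an overlapping transcript. A peak at Fas, a death receptor gene, was assigned to Gm27818, and a peak of 757 bp at Polk, a translesion DNA polymerase gene, was assigned to Col4a3bp. Peaks at Plk3, Sesn2, Rap2b and Mir34c were the others, and the Mir34c peak is the one counted above for its neighbour Mir34b. By gene span with 5 kb on each side, 33 of the 61 p53 targets had a WT-specific peak. A KO peak that no WT peak overlapped was found at 4 of 61 (6.56%), against 7.73% of all genes (odds ratio 0.838, p = 1, Fisher's exact test). Over the 61 genes, 30 had a WT-specific peak but no such KO peak, 1 had the reverse and 3 had both. An exact McNemar test, two-sided, gave p = 2.98e-08. It left out KO peaks overlapped by a WT peak but kept WT-specific peaks overlapped by a KO peak. Its sides are therefore unlike, and genes among the 30 can still have a KO peak, as Plk2 did. With the shared peak counted once, 32 of 60 genes had a WT-specific peak. Of these, 29 had no KO peak of the kind that no WT peak overlapped (exact McNemar test, p = 5.77e-08). Counting all KO peaks, whether or not a WT peak overlapped them, 11 of the 61 genes had one (18.0%, odds ratio 1.71, p = 0.106, Fisher's exact test), among them 4 of 17 cell cycle and feedback genes and 2 of 16 cell death genes. WT peaks shared with KO and outside the WT-specific list were near 7 of the 61 genes (odds ratio 2.19, p = 0.0831, Fisher's exact test).

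None of the lists outside p53 targets passed the test in the deposited annotation. Mx1, an interferon-induced antiviral GTPase, was the 1 of 20 interferon response genes with a WT-specific peak (adjusted p = 0.428, Fisher's exact test). This peak of 453 bp was intronic and overlapped an RLTR1B LTR at chromosome 16, positions 97457510 to 97457962. Tap1, which transports peptides for MHC class I, was the 1 of 13 antigen presentation genes with one, a promoter peak of 420 bp (adjusted p = 0.335, Fisher's exact test). No gene of RNA and DNA sensing (17 genes), of chemokines and cytokines (12) or of repeat silencing (24) had a WT-specific peak in the annotation (Fisher's exact test, adjusted and unadjusted p = 1 for each). Among the marker lists of other cell types, 2 of 18 neuronal and glial genes had a WT-specific peak (adjusted p = 0.0778, Fisher's exact test), among them Mbp, a myelin protein gene, in an intron, and 0 of 14 leukocyte and 0 of 11 fibroblast and endothelial genes did. By gene span with 5 kb on each side, 1 of 17 sensing, 2 of 20 interferon response, 2 of 13 antigen presentation, 0 of 12 chemokine and cytokine and 1 of 24 repeat silencing genes had a WT-specific peak. Fewer than 1 gene was expected in each of these lists, so a moderate enrichment was not detectable.

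**Figure D2:**
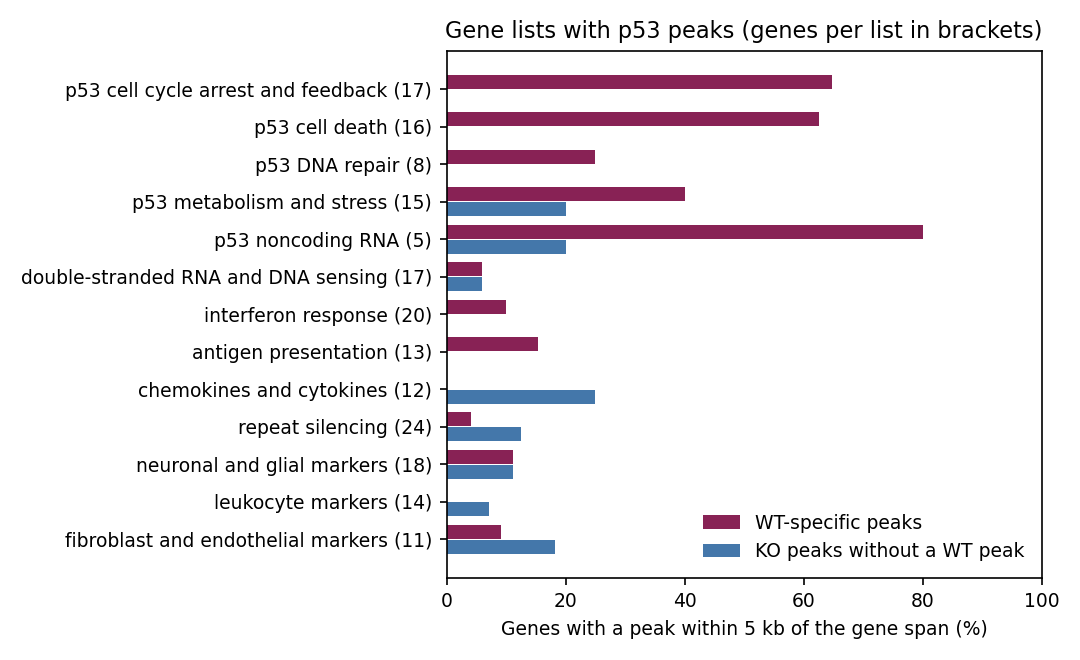
Share of each gene list (percent, horizontal axis) with a peak within 5 kb of the gene span, for WT-specific peaks and for KO peaks that no WT peak overlaps. WT-specific peaks reach 64.7% of the cell cycle arrest and feedback list and 62.5% of the cell death list, where these KO peaks reach 0% and all KO peaks, not drawn, reach 23.5% and 12.5%.

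The second comparison asked where in the genome the WT-specific peaks lie. By the deposited annotation, 1004 of 2127 (47.2%, 95% exact binomial interval 45.1 to 49.4) were intergenic, 673 (31.6%, 29.7 to 33.7) intronic and 324 (15.2%, 13.7 to 16.8) in promoters. A further 57 lay in 3' UTRs, 48 in 5' UTRs and 21 in other exons. The 10 longest WT-specific peaks included the promoters of Dyrk3, a protein kinase gene (2822 bp), Snora9 (2568 bp), Phlda3, Zfp958 (2193 bp) and Cdkn1a, and the 5' UTR of Neat1, a long noncoding RNA of paraspeckles (2424 bp). The other 4 were intergenic, 3 of them among those that overlapped a KO peak.

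The third comparison concerned repeats. The annotation placed 1444 of the 2127 WT-specific peaks, 67.9% (65.9 to 69.9), on at least 1 repeat and 683 on none. Long terminal repeats (LTRs) are the ends of endogenous retroviruses. Repeats of the LTR class, which also holds internal retroviral sequence, were in 996 peaks, 46.8% (44.7 to 49.0). SINEs were in 231 peaks (10.9%), LINEs in 97 (4.56%), simple repeats in 96 (4.51%), DNA transposons in 37 (1.74%) and satellites in 6 (0.282%). Repeats in the KO list were not analysed here, so these shares have no background measured in KO cells.

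**Figure D3:**
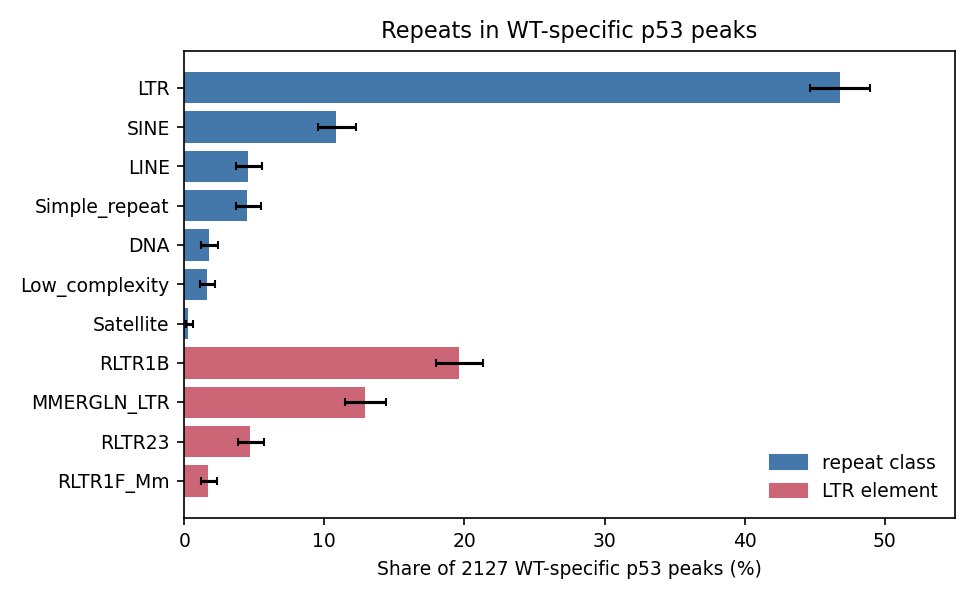
Share of WT-specific p53 peaks (percent, horizontal axis) with a repeat of each class (blue) and with each of the most frequent LTR elements (red); error bars are 95% exact binomial intervals. LTRs reach 46.8% and SINEs 10.9%, and RLTR1B alone reaches 19.6%.

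The LTR peaks were concentrated in a small number of class I endogenous retrovirus (ERV1) elements. ERV1 elements were in 851 of the 996 LTR peaks, 85.4% (83.1 to 87.6), against 78 for ERVL-MaLR, 68 for ERVK and 16 for ERVL. Among 103 distinct LTR names, RLTR1B was in 417 peaks, MMERGLN_LTR in 274, RLTR23 in 100 and RLTR1F_Mm in 36. The first 3 together were in 789 of the 996, 79.2% (76.6 to 81.7). Internal retroviral sequence, outside the LTRs, was in 48 (4.82%). The longest LTR peaks were 2568 bp at Snora9 and 2475 bp in an intergenic site on chromosome 1. Both overlapped MMERGLN_LTR, whose elements had a median length of only 430 bp, and the second also overlapped a KO peak. The next longest LTR peaks were 2311 bp overlapping an MTD element of chromosome 18, 2193 bp at Zfp958, and 2094 bp overlapping an MTA_Mm element of chromosome X. The share of these long peaks that the repeat covers was not examined. The longest LINE peaks were at Neat1, in an intergenic site of chromosome 11 (2062 bp) and in an Ephx1 intron (1857 bp). The longest SINE peaks were at Dyrk3, in an intergenic site of chromosome 4 (2641 bp) and at Neat1.

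Peaks with an LTR were more often intergenic and less often in promoters than peaks without a repeat. Of the LTR peaks, 66.7% were intergenic, against 25.6% of the 683 peaks without a repeat (odds ratio 5.81, adjusted p = 2.61e-62, two-sided Fisher's exact test across peaks). Promoters held 5.42% of the LTR peaks and 28.3% of the peaks without a repeat (odds ratio 0.146, adjusted p = 5.55e-38, Fisher's exact test). Introns held 24.4% and 36.7% (odds ratio 0.555, adjusted p = 1.27e-07, Fisher's exact test). The 448 peaks with other repeats only were left out of these contrasts. The placement of LTRs across the genome or in KO peaks was not computed. Whether these contrasts are particular to p53 peaks, rather than general to LTRs, was therefore not tested. LTR peaks had a median length of 505 bp (95% interval 493 to 524) against 373 bp (356 to 388) without a repeat, while peaks with other repeats, at 471.5 bp (444 to 520), overlapped the LTR interval. Of the 34 peaks at listed p53 targets, 4 had an LTR, against 992 of the other 2093 WT-specific peaks (47.4%; odds ratio 0.148, p = 1.67e-05, Fisher's exact test). Most of the 34 were promoter peaks, and among promoter peaks alone the difference did not pass the test: 3 of 28 had an LTR (10.7%), against 51 of 296 others (17.2%; odds ratio 0.576, p = 0.594, Fisher's exact test).

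**Figure D4:**
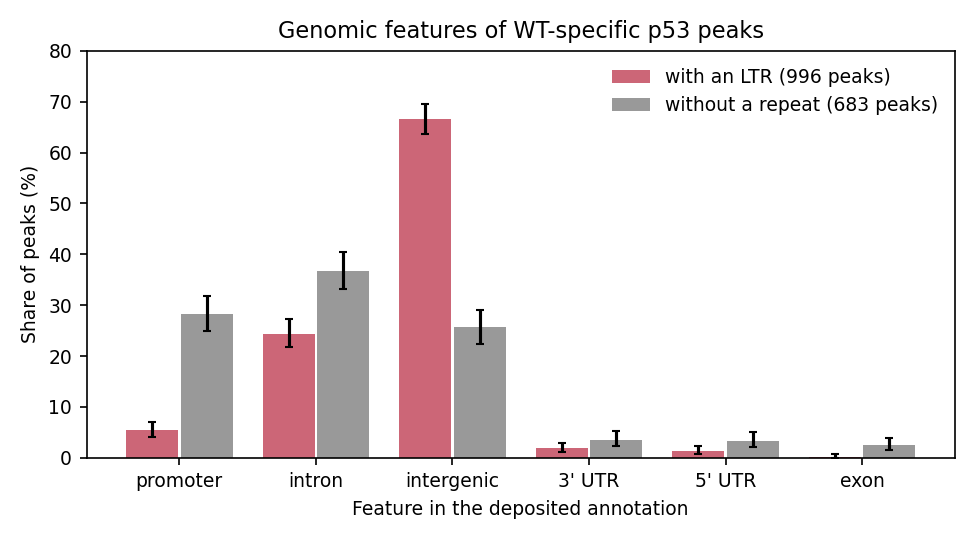
Share of WT-specific peaks (percent, vertical axis) in each feature class of the deposited annotation, for the 996 peaks with an LTR (red) and the 683 peaks without a repeat (grey); error bars are 95% exact binomial intervals. Intergenic sites hold 66.7% of the LTR peaks and 25.6% of the peaks without a repeat, and promoters hold 5.42% and 28.3%.

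Within the 3 most frequent elements, the peak midpoints fell at similar distances from the 5' end of the annotated element. The midpoint is not a measured summit. Median peak lengths were 472 bp on RLTR1B, 573.5 bp on MMERGLN_LTR and 463.5 bp on RLTR23, close to or above the element lengths. The midpoint of the peak lay a median of 101 bp from the 5' end of RLTR1B (interquartile range 74.5 to 120.5 bp), in elements with a median length of 509 bp. The medians were 107 bp in MMERGLN_LTR (72.3 to 131 bp, element length 430 bp) and 91.5 bp in RLTR23 (58.8 to 120 bp, element length 421 bp). The width of the interquartile range was 46 bp in RLTR1B, 59.1 bp in MMERGLN_LTR and 61 bp in RLTR23. RLTR1F_Mm, the next most frequent, differed in position: the median midpoint of its 36 peaks lay at -51.8 bp, outside the element, and 7 midpoints fell inside.

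**Figure D5:**
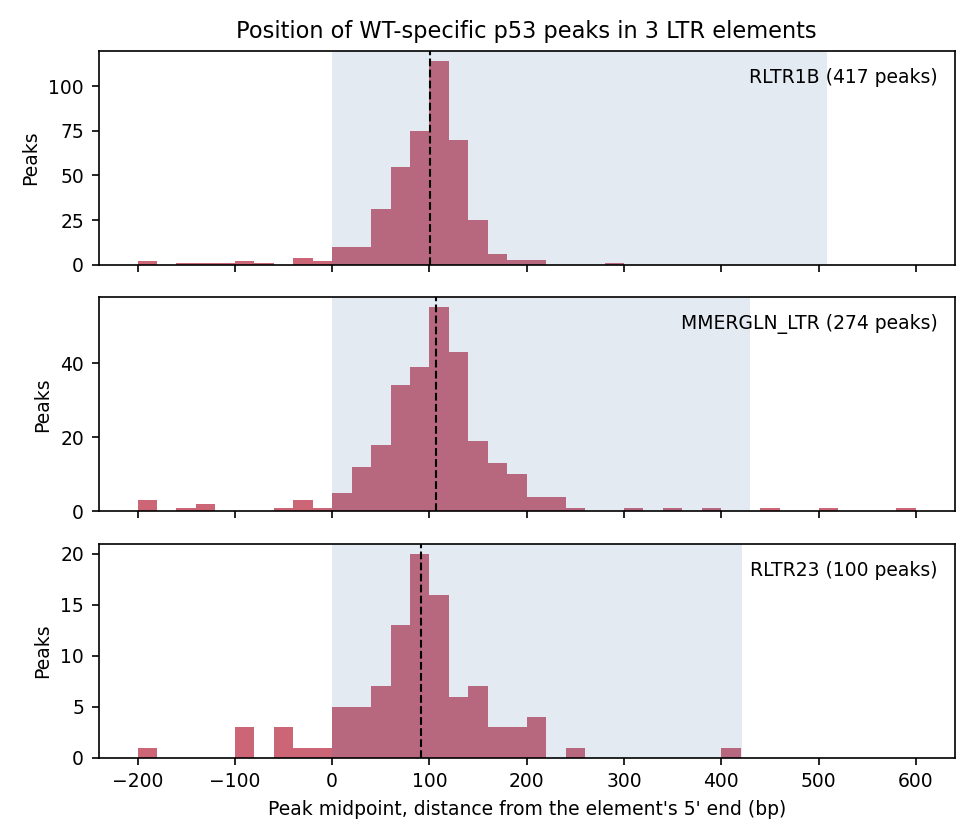
Number of WT-specific peaks (vertical axis) by the distance of the peak midpoint from the 5' end of the LTR (bp, horizontal axis, values past the axis placed in the end bins) for RLTR1B, MMERGLN_LTR and RLTR23. Blue shading marks the median element length and the dashed line the median midpoint, which lies at 101, 107 and 91.5 bp.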

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

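The counts of p53 targets with a WT-specific peak and of enriched lists kept their direction and stayed within 1.5 times of the reported values under each alternative run. The share of WT peaks without a KO peak, 40.6% as reported, was 43.1% where 50% of the WT peak had to be overlapped and 40.5% without chromosomes Y and M, and 2722 of 6811 peaks were left where KO peaks within 500 bp also counted. It rose to 55.6% (1889 of 3400) with the longer 50% of each list and to 49.5% (1684 of 3400) with the longer 50% of the WT list against all KO peaks. Listed p53 targets with a WT-specific peak ranged from 23 (promoter class only) to 33 (gene span with 5 kb), with odds ratios from 22.3 to 158. Enriched lists numbered 4 with the other peak choices and, in the 1062 longest WT-specific peaks, 5, where the neuronal and glial list passed as well (2 of 18 genes, adjusted p = 0.0212, Fisher's exact test). Over the alternatives its adjusted p ranged from 0.0212 to 1, and in the reported setting its count stood at percentile 85.3 of random lists matched on gene length. With protein-coding genes as background, 3 lists were enriched, since the list of noncoding RNA genes then had no members. With an overlap of at least 50% of the peak, 34 and not 71 WT-specific peaks overlapped a KO peak. The median length of WT-specific peaks was 398 bp when all WT peaks without a KO peak were taken. Leaving out the 71 peaks that overlap a KO peak alone gave 450 bp, and adding the 712 shorter peaks gave the rest of the move. The promoter share rose to 17.5% with 5' UTRs added. The share of peaks with a repeat was 44.9% where repeats had to cover 50% of the peak, 62.8% without simple and low complexity repeats, and 78.0% in the 1062 longest peaks. The LTR share was 38.8% with 50% of the peak covered, 40.9% with the midpoint inside, and 55.7% in the 1062 longest peaks. Fewer LTRs at p53 targets passed the test over all peaks (odds ratio 0.148) and not among promoter peaks alone (0.576, p = 0.594, Fisher's exact test). The cause of the higher shares in long peaks was not tested. The alternatives that use the longer peaks, the promoter class, 5' UTRs or the gene span, or leave out peaks on chromosome Y, on chromosome M or at KO peaks, were chosen after seeing the data. Alternatives that need a score, a fold, a distance to the transcription start site or an mm10 sequence were not run. No paired analysis was possible because each genotype has 1 peak list with no values per replicate, and for the same reason no replicate could be left out. Depth is unknown, so a site below the caller's threshold cannot be told from one without binding.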

Other observations

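The tests of a fixed position in LTRs, of LTR edges, of reads shared between LTR copies and of repeats on chromosome Y were chosen only after the result was seen. Outside the fixed lists, the annotation gave WT-specific promoter peaks to further genes, named here after their values were seen. Rps27l (858 bp), Zfp365 (553 bp), Aldh4a1 (229 bp), Ptp4a1 (958 bp), Lif (1160 bp) and Glipr1 (1547 and 192 bp) are described as p53 targets in human or mouse cells. The growth factor gene Areg (217 bp) and the receptor kinase gene Met (253 bp) also had one. So did the tumour suppressor gene Rb1 (515 bp) and the glucocorticoid receptor gene Nr3c1 (388 bp). None of the peaks named here overlapped a KO peak, but only 3.34% of all WT-specific peaks did, so this says little about these genes.

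Whether LTR peaks lie near genes of RNA sensing, interferon response, antigen presentation and chemokines was tested at a distance of 50 kb. Such a peak was found near 6 of 62 genes (Adar, Bst2, Il6, Mx1, Mx2 and Oas1a), against a median of 3 and a 95th percentile of 6 in 10000 random lists matched on gene length, so 10.8% of random lists had as many or more and the question stays open. The p53 target lists, for which no bound was set beforehand, had 8 of 61 genes near an LTR peak, at percentile 98.2. Among the 8, Mdm2, Mdm4, Gtse1 and Psrc1 had the LTR in a WT-specific peak already counted at the gene. The percentile therefore partly restates the enrichment of p53 targets and is no separate evidence about LTRs. Of 24 repeat silencing genes, 1 (Zfp809, a zinc finger gene that represses retroviruses) had a WT-specific peak within 5 kb. The random lists had a median of 1 and a 5th to 95th percentile range of 0 to 4, so the bound set beforehand, the random median, was met within this spread and excludes nothing.

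The position of peaks within RLTR1B, MMERGLN_LTR and RLTR23 is a candidate for follow-up. Reads placed at both LTR edges alike would give midpoints near either end. Yet 97.9% of the 752 midpoints inside an element lay nearer its 5' end (95% interval 96.6 to 98.8), and with midpoints outside included 97.3% of 791 did (96.0 to 98.3). Even use of both edges thus does not account for the position, while placement of reads that favours the 5' edge was not tested. Reads shared between LTR copies stay open: 92.4% of 789 peaks reached at least 50 bp past the 5' end and 11.8% past the 3' end, but the midpoint and the length of the peaks already set these shares. A binding sequence at a fixed place also stays open, since the widest interquartile range of 61 bp, against at least 173 bp with shuffled strands, restates the observed side, and RLTR1F_Mm, with most midpoints outside the element, gave 88.4 against at least 132 bp. Of 59 pairs of neighbouring peaks on the same element 3 to 12 kb apart, 100% were on the same strand (95% interval 93.9 to 100%), 47 of them on MMERGLN_LTR at a median distance of 7959 bp. This fits peaks on both LTRs of 1 provirus, but reads shared between its LTR copies would give the same pairs. Peaks in such a pair are not independent, although the intervals treat them so.

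WT-only and KO-only peaks were split unevenly between chromosomes: the ratio of WT peaks without a KO peak to KO peaks without a WT peak was 1.80 on chromosome 19 and 0.990 on chromosome 6, and 0.272 on chromosome 7 and 0.275 on chromosome 18. Across 20 chromosomes this ratio rose with the median width ratio (WT over KO) of peaks present in both lists (Pearson r = 0.835, permutation p = 1e-05, the smallest that 100000 permutations can give; Spearman rho = 0.881, permutation p = 2e-05; r = 0.814 without the 2 most extreme chromosomes; adjusted p over 4 relations 2e-05 and 4e-05), which fits a copy number difference between the WT and KO cells as a hypothesis, while other differences along whole chromosomes between the libraries were not tested. Uneven p53 sites as the whole cause are argued against by the KO-only peaks, whose ratio to shared KO peaks fell with the same width ratio (r = -0.793, rho = -0.841, permutation p = 5e-05 and 3e-05; r = -0.765 without the 2 most extreme). A partial share stays open: WT-only peaks outside the WT-specific list, over KO-only peaks, correlated with WT-specific over shared WT peaks at r = 0.287 and rho = 0.211 (permutation p = 0.220 and 0.375; r = 0.268 without the 2 most extreme), which decides neither way. A bound set beforehand against it, on the correlation of that ratio with WT-specific over KO-only peaks, was passed at rho = 0.887, but it was wrongly chosen, since both ratios divide by the KO-only count, which builds in a correlation.

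Chromosome Y held 25 WT peaks and 25 WT-specific peaks, 5 of which overlapped a KO peak, although the line comes from ovarian tissue, where no chromosome Y is expected. Reads from near-identical repeat copies elsewhere may be the source, as a hypothesis, since these repeats were picked after they had been seen: 76% of these peaks (19 of 25, 95% interval 54.9 to 90.6) held a B1_Mus1 element or a GAAA or TTTC tract, against 2.09% of the 2102 WT-specific peaks elsewhere, and 15 of the B1_Mus1 copies, found in 16 of these peaks, had the same length of 141 bp. The KO list had 7 peaks on chromosome Y. Why WT had more was not examined, and no biological explanation was tested. Removing chromosome Y together with the KO-overlapping peaks left the LTR share at 48.2%. In 1 further region, chosen after its values were seen (chromosome 10, positions 86000001 to 87000000), 11 of 13 WT peaks were WT-specific, 7 of them in introns of Syn3, with 1 KO peak.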
